A study of Homo sapiens with 9 samples.

How the data were processed

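RNA-seq was carried out on MM1S cells, an established human multiple myeloma line, and 9 libraries were analysed. Per the labels, cells were infected with lentivirus carrying either an empty vector or an shRNA against PHF19, total RNA was purified with a column kit, and libraries were made from 1 µg of total RNA with an Illumina TruSeq kit. The labels place 3 libraries in the empty vector control (shEV), 3 in the PHF19 knockdown (PHF19_KD) and 2 in the knockdown with shRNA-resistant PHF19 added back (KD_Rescued). The labels of 1 further library disagree: its title calls it a knockdown, and its shRNA label names shRNA-resistant PHF19. It was kept apart as a group of 1 and left out of every test.

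The deposited table holds estimated counts per gene, with 1 column per library and 58387 genes, and the authors had not scaled them between libraries. CASAVA, RSEM and hg19 are named in the submitters' processing notes without roles or versions, while the name of the deposited table refers to salmon, so which program made the estimated counts is not settled. The annotation, the filters and the strand setting are not given in the sources used here. Between 15.6% and 19.4% of the values of a library were not whole numbers within a tolerance of 0.01, which arises where reads are divided among genes. This share is over all 58387 genes, those with 0 counts included, and was larger among expressed genes. Of 15051 genes with a sum of at least 20 in shEV replicates 1 and 2, 6783 were whole in both. Genes with such values in several libraries (pseudogenes, readthrough transcripts and members of families) are named as uncertain below, and without a stated strand setting the reads of overlapping and antisense genes cannot be told apart either. Genes are identified by the symbols of the table. It gives no coordinates, and the annotation at hand (GENCODE 29) is on a different build, so no positions are given.

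Column totals ran from 10164100 to 23751400 counts. The estimated counts were rounded to whole numbers and tested with the edgeR quasi-likelihood method (edgeR 4.0.16, R 4.3.3). The steps were filterByExpr by group, TMM scaling, robust dispersions, glmQLFit with robust estimation, and glmQLFTest. All 8 libraries with undisputed labels entered a single fit with group means and no further terms, so that KD_Rescued, with 2 libraries, borrowed the spread of the other groups. The filter left 16600 genes. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called changed. Standard errors of log2 fold changes were taken as the fold change divided by the square root of the F statistic. Normalised CPM are scaled by column total and TMM factor, and their SD is between libraries of a group. For a gene with 0 counts in all libraries of a group, a bound on the fold was computed from a floor of 3 counts over the group.

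The genes named in the text followed a rule. PHF19 was named, then the 10 largest rises and the 10 largest falls in log2 fold change per comparison, and at most 4 members of each gene list, namely the 2 called rises and the 2 called falls with the lowest adjusted p or, where no member was called, the 2 with the highest mean level. The largest changes had to be called, to have a mean log2 CPM of at least 1, and to have no overlap between the libraries of both groups. Any gene outside this rule is said to be so. The text gives a part of the genes that met the rule. There were 30 gene lists, covering Polycomb subunits and targets, cell cycle, myeloma and B-lineage identity, interferon response, antigen presentation, stress responses, metabolism, ribosomal proteins, histones and markers of other cell types. They were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists within a comparison. The same test with an estimated correlation and the rotation test fry were run beside it. The groups, tests, lists, naming rule and first set of alternatives were fixed before the data were examined.

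The labels do not say that replicates were separate cultures, and the 3 PHF19_KD libraries share a name stem, so p-values measure the spread between these libraries, which may be technical. Each pair of replicates differed by more than counting noise. The chi-square per degree of freedom was between 1.37 and 9.80 over genes with whole counts and a sum of at least 20, with shEV replicate 3 farthest from its group, so every library was counted separately. Per the library names, both KD_Rescued libraries were run in a different lane from all other libraries, so lane and rescue cannot be told apart.

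The tests were checked on simulated counts for PHF19_KD against shEV over 16600 genes. The simulation took each gene's mean over the 8 fitted libraries and their library sizes. Of 50 genes changed at each size, 34% were recovered at 1.25-fold, 82% at 1.5-fold, 88% at 2-fold and 100% at 4-fold, and 8.42% of the calls were unchanged genes. Of 100 random lists, 0 passed the list test. Few genes were changed in the simulation, against 69.1% called between PHF19_KD and shEV, so these shares do not carry over to the data. Genes were drawn independently, so the random lists do not check the preset correlation.

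The alternatives were RLE and upper-quartile scaling, no filter, a filter at 5 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, fits of only the groups compared, the library with disagreeing labels counted as PHF19_KD or as KD_Rescued, replicate number as a block, a minimum change of 2-fold, and leaving out each library in turn. Thinning all libraries to equal depth, removing mitochondrially encoded genes and parting shared libraries were chosen after seeing the data. Because the comparisons share libraries, chance values for their covariance and correlation came from 20 simulated sets of unchanged groups. For the overlap of calls, the libraries of the shared group were parted between the comparisons, 1 for one and 2 for the other, in each of the 6 ways.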

Results

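The transcriptome of MM1S myeloma cells was measured by RNA-seq in empty vector controls (shEV, n = 3), in cells with a PHF19 knockdown (PHF19_KD, n = 3) and in knockdown cells given shRNA-resistant PHF19 (KD_Rescued, n = 2). PHF19 is an accessory subunit of Polycomb repressive complex 2 (PRC2), the complex that methylates histone H3 at lysine 27. The libraries held from 16974700 to 22739700 counts in shEV, from 10609800 to 12024900 in PHF19_KD and from 23644100 to 23751400 in KD_Rescued. The library with disagreeing labels held 10164100.

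PHF19 itself followed the labels. Its normalised level was 117 ± 11.8 CPM in shEV (SD, n = 3), 26.9 ± 0.860 CPM in PHF19_KD (SD, n = 3) and 219 ± 1.74 CPM in KD_Rescued (SD, n = 2). The knockdown thus left 23.1% of the control level, and the rescued cells held 188% of it. The log2 fold change was -2.11 ± 0.08 (SE) between PHF19_KD and shEV (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.47e-10), 3.02 ± 0.08 between KD_Rescued and PHF19_KD (adjusted p = 2.49e-11, same test) and 0.91 ± 0.07 between KD_Rescued and shEV (adjusted p = 2.46e-06, same test). The count does not separate the endogenous transcript from the introduced construct. The library with disagreeing labels held 63.6 CPM, which is 54.5% of the shEV mean and lies outside the range of every group. Counting that library as PHF19_KD or as KD_Rescued ended the call between KD_Rescued and shEV, at log2 fold changes of 0.86 and 0.49.

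**Figure D1:**
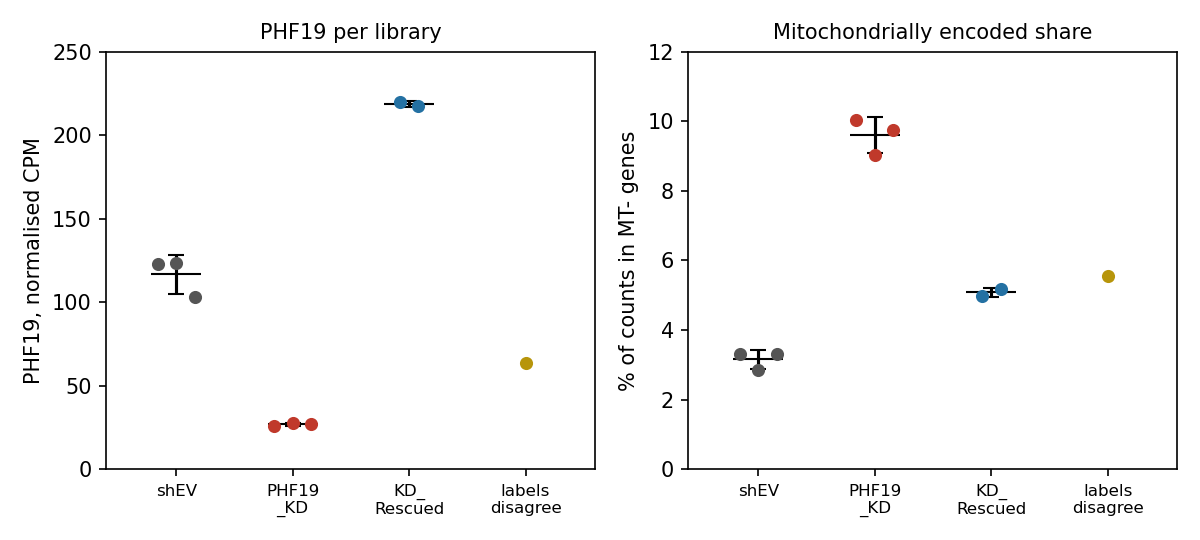
Left, PHF19 in normalised CPM for each library (points), and right, the percentage of each library's counts in mitochondrially encoded genes, by group, with the mean and SD as bars where a group has more than 1 library. The PHF19_KD libraries sit lowest for PHF19, at 26.9 CPM on average, and highest for the mitochondrial share, at 9.60%.

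The first comparison asked which transcripts differ when PHF19 is depleted. Cell cycle genes fell most uniformly. All 46 measured genes of DNA replication and G1/S fell, with a median log2 fold change of -3.05, as did all 42 measured genes of G2/M and mitosis, with a median of -2.86. RRM2, which encodes a subunit of ribonucleotide reductase, went from 739 ± 11.4 CPM in shEV to 28.5 ± 0.688 CPM in PHF19_KD (SD, n = 3 each), and its count shares reads with related sequences. MCM4, a subunit of the replicative helicase that also shares reads, changed by -3.91 ± 0.05 on the log2 scale (SE), CDC6, which loads that helicase, by -4.84 ± 0.09, the mitotic checkpoint kinase gene BUB1 by -3.14 ± 0.05, and the proliferation marker MKI67 by -3.48 ± 0.06. Both lists passed camera with the preset correlation (adjusted p = 2.54e-22 and 1.14e-20) and with an estimated one (adjusted p = 0.0168 and 0.0290). Within the Polycomb machinery, EZH2, the main catalytic subunit of PRC2, changed by -2.02 ± 0.06, and its paralog EZH1 by 0.91 ± 0.06.

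MYC targets and unfolded protein response genes were mostly lower. Of 40 MYC targets, 37 fell and 0 rose, with a median of -0.78, including LDHA (lactate dehydrogenase, -2.29 ± 0.04, SE) and the transferrin receptor gene TFRC (-1.41 ± 0.05). Of 28 unfolded protein response genes, 22 fell and 3 rose, with a median of -0.73. SEC24D, a coat protein of vesicles leaving the endoplasmic reticulum, changed by -1.30 ± 0.04, while the stress sensor gene ERN1 changed by 0.81 ± 0.04. Both lists passed camera with the preset correlation (adjusted p = 9.82e-11 and 2.95e-05) and with an estimated one (adjusted p = 0.0443 and 0.0290). Of 27 ATF4 and amino acid stress genes, 19 fell and 4 rose, the serine synthesis gene PHGDH among the falls (-4.23 ± 0.11) and GADD45A among the rises (2.28 ± 0.05), with adjusted p = 0.112 with an estimated correlation. Nuclear-encoded oxidative phosphorylation genes fell in 30 of 41 cases and rose in 2, with adjusted p = 0.226 with an estimated correlation. Of 33 plasma cell identity genes, 18 fell and 7 rose. Among them were the surface receptor gene GPRC5D at -2.33 ± 0.08 and, in the opposite direction, CD38 at 1.16 ± 0.04, with adjusted p = 0.105 for the list with an estimated correlation.

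Interferon-stimulated genes and antigen presentation genes were higher in the knockdown. Of 56 interferon-stimulated genes, 43 rose and 6 fell, with a median log2 fold change of 0.86. The antiviral GTPase gene MX1 went from 11.8 ± 0.719 to 59.6 ± 1.55 CPM, and IFI6 from 3.47 ± 0.609 to 54.0 ± 4.91 CPM (SD, n = 3 each). The list passed camera with the preset correlation (adjusted p = 3.26e-07) and with an estimated one (adjusted p = 0.0168). Of 14 MHC class II genes, 12 rose and 1 fell, with a median of 0.92 and adjusted p = 0.103 with an estimated correlation. HLA-DQB1 changed by 3.75 ± 0.11 (SE) and HLA-DOB by 2.91 ± 0.11, although HLA genes share reads with one another. Of 18 MHC class I genes, 13 rose and 2 fell (adjusted p = 0.308 with an estimated correlation), the falls being the endoplasmic reticulum chaperone genes CALR (-0.94 ± 0.04) and PDIA3 (-0.69 ± 0.05).

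Several further groups passed with the preset correlation but not with an estimated one. Cytosolic ribosomal protein genes rose in 45 of 52 cases and fell in 0, with a median of 0.43 (adjusted p = 0.316 with an estimated correlation). Immediate early genes rose in 13 of 19 cases and fell in 1, DUSP1 by 1.75 ± 0.05 (adjusted p = 0.0698 with an estimated correlation). NF-kB targets rose in 18 of 31 cases and fell in 5, with TRAF1 at 3.11 ± 0.11 and the chemokine gene CCL3 at -1.70 ± 0.05 (adjusted p = 0.197 with an estimated correlation). Of 26 p53 targets and cell cycle inhibitors, 17 rose and 6 fell (adjusted p = 0.112 with an estimated correlation). Counting the library with disagreeing labels as PHF19_KD ended the preset-correlation calls of the immediate early, plasma cell and erythroid lists (camera adjusted p = 0.0783, 0.0744 and 0.0562) and that of CCL3, counting it as KD_Rescued ended that of the p53 list (camera adjusted p = 0.121), and a filter at 5 CPM that of the plasma cell list (camera adjusted p = 0.0873). The 3 measured erythroid markers fell, 2 of which were the globin genes HBD and HBB, which share reads (adjusted p = 0.148 with an estimated correlation, and camera adjusted p = 0.184 without a filter).

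Developmental Polycomb targets went both ways. Of the 99 genes of that list 37 were measured, and 10 of these rose and 12 fell, with a median of -0.12. The list did not pass against other genes (camera adjusted p = 0.560 at the preset correlation), and fry, which makes no such comparison, called it as lower (Benjamini-Hochberg adjusted p = 0.00258). In this comparison fry also called most other lists, as higher or as lower, so its call is not particular to the Polycomb targets. The rises included HOXB3 at 1.38 ± 0.12 (SE) and HOXC4 at 2.19 ± 0.41, and the falls included the cyclin gene CCND2 at -2.02 ± 0.05 and SOX2 at -1.63 ± 0.10. PRC2 subunits rose in 3 and fell in 8 of 12 cases (camera adjusted p = 0.0551), and the list passed with upper-quartile scaling, without a filter and with the library of disagreeing labels counted as PHF19_KD (camera adjusted p = 0.0457, 0.00997 and 0.0476). PRC1 subunits rose in 6 and fell in 12 of 22 cases (camera adjusted p = 0.273). Lists that also missed the camera threshold at the preset correlation, with their rises and falls, were the MAF program (9 and 8), B cell identity (8 and 4), the BCL2 family (8 and 5), JAK-STAT signalling (17 and 5), cholesterol synthesis (8 and 13), glycolysis and hypoxia (9 and 12), histones (5 and 2) and heat shock (3 and 9). Of these, JAK-STAT signalling passed with upper-quartile scaling and with a filter at 5 CPM (camera adjusted p = 0.0399 and 0.0466), cholesterol synthesis without a filter (camera adjusted p = 0.0374), and heat shock without a filter and without shEV replicate 3 (camera adjusted p = 0.00794 and 0.0262). The markers of T and NK cells (1 and 1), monocytes (2 and 0), epithelial cells (2 and 1) and fibroblasts (2 and 3) missed it too. The median and mean log2 fold changes differed in sign for the T and NK markers (-0.33 and 0.06) and for the fibroblast markers (-0.19 and 0.44). Adjusted over the list alone, the rises and falls were the same in each list except the p53 targets (18 and 6), the BCL2 family (9 and 5), oxidative phosphorylation (3 and 31) and ribosomal proteins (46 and 0).

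Among single genes, the largest rises were those of the interleukin 23 receptor gene IL23R, which went from 0.0319 ± 0.0278 to 7.27 ± 0.506 CPM, UBD (6.10 ± 0.58, log2 and SE), AZGP1 (5.71 ± 0.23), SSPO (5.46 ± 0.28), the kinase gene DAPK2 (5.33 ± 0.27), the fructose transporter gene SLC2A5 (5.22 ± 0.16), LRP1 (4.79 ± 0.14), the mitochondrial tRNA gene MT-TF (4.69 ± 0.16) and CYP1A1 (4.62 ± 0.20). RP11-514P8.8 met the rule too, but its reads were divided among genes in 8 of the 9 libraries, and its call was lost with limma-voom (Benjamini-Hochberg adjusted p = 0.118). The largest falls included the vesicular nucleotide transporter gene SLC17A9, which went from 9.55 ± 0.231 to 0.0289 ± 0.0501 CPM, the tyrosine kinase gene FES (-5.92 ± 0.48), AIF1L (-5.72 ± 0.46), the polysialyltransferase gene ST8SIA2 (-5.26 ± 0.22) and FAM189A1 (-5.05 ± 0.32). The pseudogene CKS1BP3 had 0 counts in all PHF19_KD libraries and was at least 103-fold lower there and SENP3-EIF4A1 at least 48.7-fold lower, while LLfos-48D6.2 also had 0 counts there and 2.53 ± 1.27 CPM in shEV. These 3 and CH507-254M2.2 share reads with other genes and are uncertain. The counts of EZH2, LDHA, CD38, MX1, CALR, PDIA3, CCL3, HOXB3, CCND2 and UBD share reads too and are uncertain.

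In all, 11476 of 16600 tested genes changed between PHF19_KD and shEV, 5793 of them higher and 5683 lower (edgeR quasi-likelihood, Benjamini-Hochberg). Of these 4383 changed at least 2-fold, 2712 up and 1671 down, and the libraries of both groups did not overlap for 72.0% of the tested genes, against 10% by chance. Upper-quartile scaling raised the median log2 fold change of all genes from 0.03 to 0.19 and the share of higher calls from 50.5% to 60.6%. That share was 46.4% without a filter, 48.6% without mitochondrially encoded genes and 49.0% with DESeq2, so the majority direction depended on the processing. Beside these changes, mitochondrially encoded genes took 9.60% ± 0.518 of the counts in PHF19_KD and 3.16% ± 0.279 in shEV (SD, n = 3 each).

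**Figure D2:**
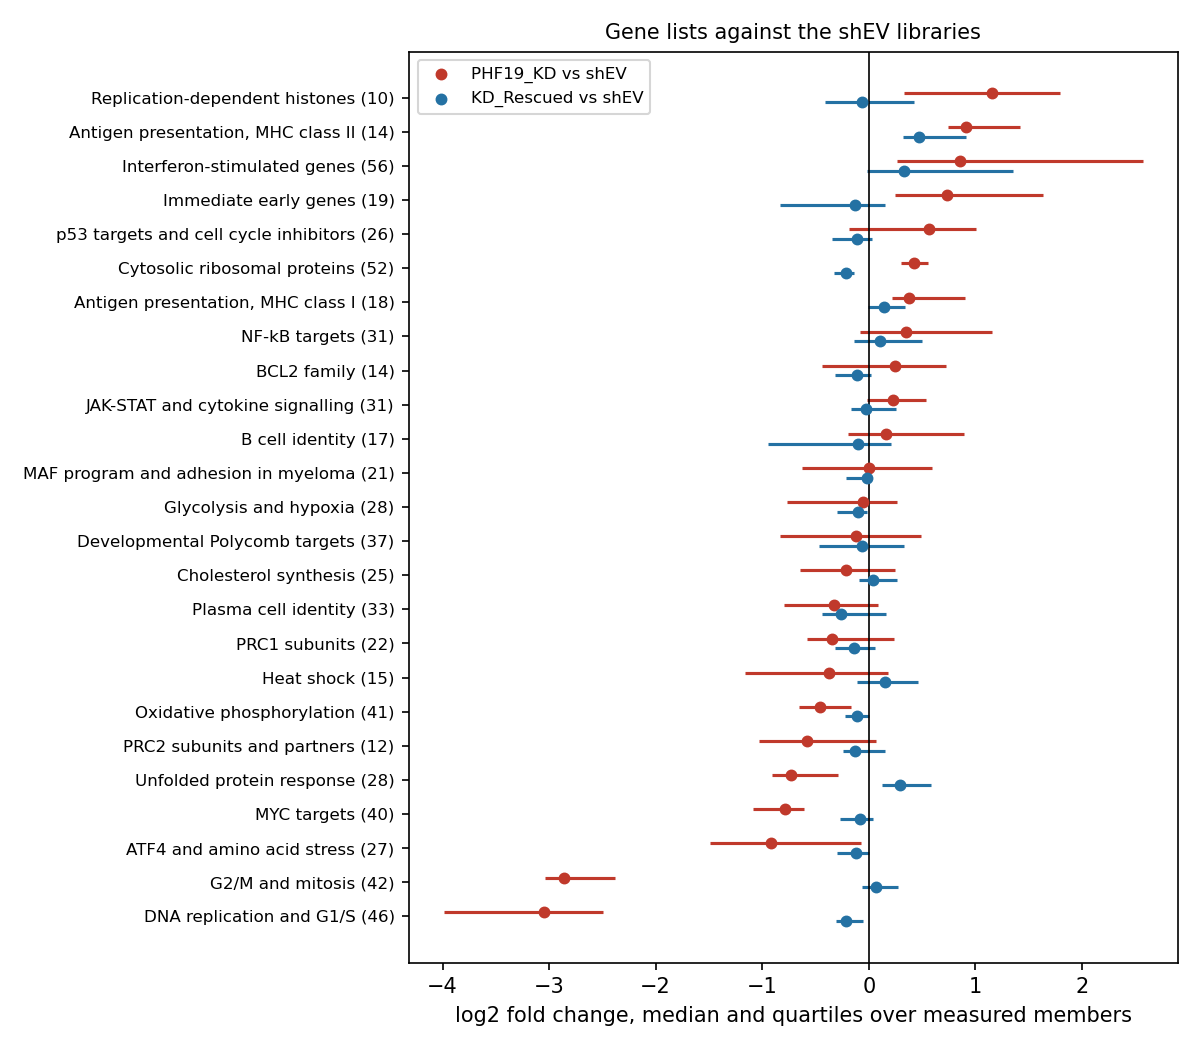
Median log2 fold change (points) and quartiles (bars) over the measured members of each gene list with at least 10 of them, for PHF19_KD against shEV and for KD_Rescued against shEV, with the number of members in brackets. The cell cycle lists lie near -3.05 and -2.86 in the knockdown and at -0.22 and 0.06 after rescue, while the interferon-stimulated genes lie at 0.86 and 0.33.

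The second comparison asked what the return of PHF19 changed in knockdown cells. All 46 replication genes and all 42 mitosis genes rose, with medians of 2.90 and 2.94 (camera adjusted p = 1.68e-22 and 6.67e-22, and 0.0186 and 0.0212 with an estimated correlation). RRM2 reached 571 ± 5.41 CPM and MKI67 613 ± 15.7 CPM (SD, n = 2 each). CDC6 changed by 4.89 ± 0.09 (SE), CDCA7 by 5.13 ± 0.11 and UHRF1, a partner of maintenance DNA methylation that shares reads, by 4.41 ± 0.11. EZH2 rose by 2.14 ± 0.06. Unfolded protein response genes rose in 24 of 28 cases and fell in 3, with a median of 0.99 (camera adjusted p = 2.71e-07, and 0.0212 with an estimated correlation), the secreted factor gene MANF by 1.97 ± 0.05. MYC targets rose in 37 of 40 cases and fell in 2 (adjusted p = 0.0542 with an estimated correlation), although MYC itself changed by -0.47 ± 0.05.

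Interferon-stimulated genes fell in 36 of 56 cases and rose in 9, with a median of -0.63 (camera adjusted p = 2.14e-05, and 0.0212 with an estimated correlation). The guanylate-binding protein genes GBP4 and GBP2, which share reads, changed by -3.03 ± 0.12 and -3.13 ± 0.15 (SE), whereas the chemokine gene CXCL10 changed by 1.99 ± 0.11. Immediate early genes fell in 15 of 19 cases and rose in 1 (camera adjusted p = 2.14e-05, and 0.0252 with an estimated correlation). FOS went from 18.7 ± 0.986 CPM in PHF19_KD (SD, n = 3) to 0.125 ± 0.000300 CPM in KD_Rescued (SD, n = 2), FOSB changed by -5.03 ± 0.28 and DUSP1 by -4.16 ± 0.07. Ribosomal protein genes fell in 49 of 52 cases and rose in 0, with a median of -0.66 (adjusted p = 0.234 with an estimated correlation). MHC class II genes fell in 11 of 14 cases and rose in 2 (adjusted p = 0.198 with an estimated correlation), and p53 targets fell in 17 of 26 and rose in 6, CDKN1A by -1.56 ± 0.07 among the falls (adjusted p = 0.0542 with an estimated correlation). Further lists passed with the preset correlation only. Heat shock genes rose in 10 of 15 cases and fell in 1, ATF4 and amino acid stress genes rose in 18 of 27 and fell in 6, and oxidative phosphorylation genes rose in 29 of 41 and fell in 4 (adjusted p = 0.0674, 0.198 and 0.323 with an estimated correlation). MHC class I genes fell in 13 of 18 cases and rose in 2 (adjusted p = 0.298 with an estimated correlation). Among markers of other cell types, all 3 measured erythroid markers rose (camera adjusted p = 0.0183, and 0.150 with an estimated correlation) and both measured monocyte markers fell, CD68, which shares reads, by -1.52 ± 0.10 and ITGAM by -2.07 ± 0.30 (camera adjusted p = 0.0536). The call of the ATF4 list was lost with the library of disagreeing labels counted as PHF19_KD, and that of the erythroid markers without a filter (camera adjusted p = 0.0616 and 0.0506). The monocyte list passed with that library counted as PHF19_KD, without shEV replicate 2 and without PHF19_KD replicate 1 (camera adjusted p = 0.0291, 0.0455 and 0.0420). B cell identity and NF-kB targets missed the threshold (camera adjusted p = 0.0536 for both). They were called as lower with a replicate block (camera adjusted p = 0.0488 for both) and under further alternatives. Adjusted over the list alone, the lists with counts given for this comparison kept them except the falls of the interferon-stimulated genes (37) and of the p53 targets (18) and the rises of the oxidative phosphorylation genes (31). With the library of disagreeing labels counted as KD_Rescued, the calls of CXCL10, CDKN1A and IL23R were lost (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0830, 0.0747 and 0.0715). So were those of both monocyte markers, CD68 and ITGAM (adjusted p = 0.153 and 0.0750, same test).

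The largest single falls included genes that had risen most in the knockdown, namely IL23R (-8.03 ± 0.48, log2 and SE), SLC2A5 (-6.32 ± 0.20), DAPK2 (-6.00 ± 0.33), CYP1A1 (-5.51 ± 0.25), LRP1 (-5.37 ± 0.17) and SSPO (-5.00 ± 0.30), as well as the collagen chaperone gene FKBP10 (-5.50 ± 0.86). The largest rises included the procollagen protease gene ADAMTS2, at 12.3 ± 0.471 CPM in KD_Rescued and 0.0599 ± 0.0520 CPM in PHF19_KD, and the collagen gene COL6A3, at 7.24 ± 4.17 CPM (SD, n = 2) and 0.0841 ± 0.0828 CPM (SD, n = 3). CKS1BP3, SENP3-EIF4A1 and LLfos-48D6.2, with 0 counts in PHF19_KD, were at least 106-fold, 50.3-fold and 40.8-fold higher after rescue, with shared reads as above. AC009133.21 and CH507-254M2.2 also met the rule and share reads. In all, 10526 of 16600 genes changed, 5622 higher and 4904 lower (edgeR quasi-likelihood, Benjamini-Hochberg), and 3849 of them at least 2-fold. The share of higher calls was 53.4%, and 42.1% with upper-quartile scaling. Counting the library with disagreeing labels as KD_Rescued left 6207 calls.

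**Figure D3:**
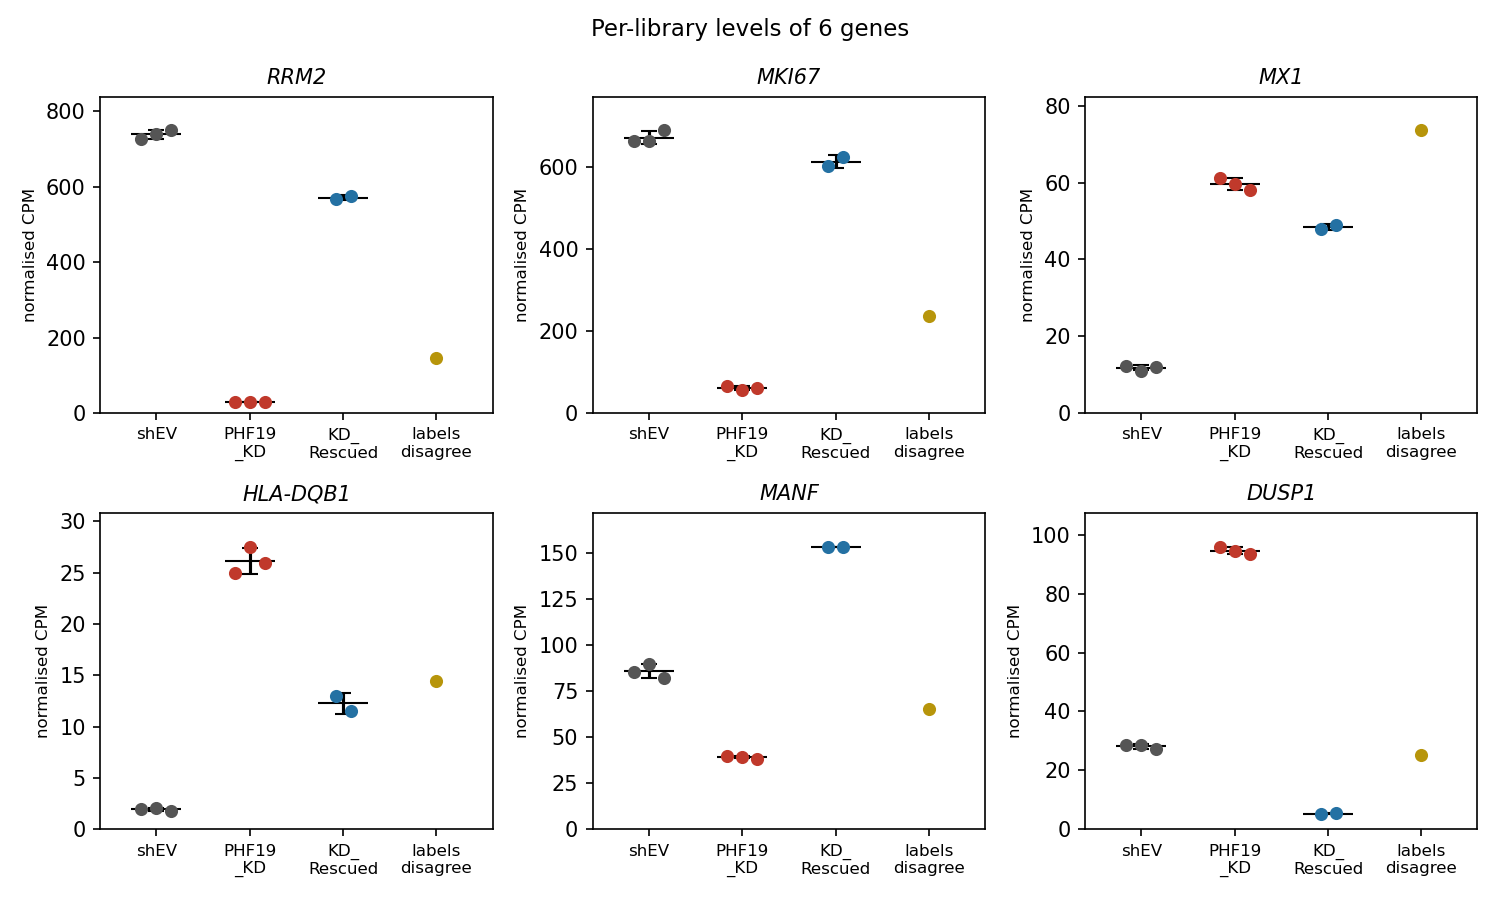
Normalised CPM on a linear axis from 0 for RRM2, MKI67, MX1, HLA-DQB1, MANF and DUSP1 in each library (points), by group, with the mean and SD as bars where a group has more than 1 library. RRM2 and MKI67 return towards the shEV level after rescue, MX1 stays at 48.5 CPM against 11.8 CPM in shEV, and DUSP1 lies below shEV at 5.29 CPM.

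Of the 11476 genes changed by the knockdown, 8536 (74.4%) were called in the opposite direction after rescue. This held for 4534 of 5683 lowered genes (79.8%) and 4002 of 5793 raised genes (69.1%). Independent lists of the same sizes would share 3636 genes called in opposite directions. Both comparisons contain the PHF19_KD libraries. With these parted so that no library was in both comparisons, from 6926 to 7142 genes moved back over the 6 ways to part them. Across genes the log2 fold changes of the comparisons had a covariance of -1.18 against a simulated mean of -0.07, a difference of -1.10, and a correlation of -0.80 against a simulated mean of -0.50. Of the genes that moved back, 5285 were not called between KD_Rescued and shEV. With the library of disagreeing labels counted as KD_Rescued, 5400 genes moved back.

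The third comparison asked what still differed from control cells after rescue. Interferon-stimulated and MHC class II genes were still higher. Of 56 interferon-stimulated genes, 27 rose and 6 fell relative to shEV, with a median of 0.33 (camera adjusted p = 0.000159, and 0.0695 with an estimated correlation). MX1 was at 48.5 ± 0.764 CPM (SD, n = 2), and XAF1 changed by 2.62 ± 0.11 (SE). Of 14 MHC class II genes, 12 rose and 1 fell, with a median of 0.48 (camera adjusted p = 9.39e-06, and 0.110 with an estimated correlation), HLA-DQA1 by 2.64 ± 0.11 and HLA-DQB1 by 2.66 ± 0.12, both with shared reads. Unfolded protein response genes were above control in 21 of 28 cases and below it in 4, with a median of 0.29 (camera adjusted p = 0.000159, and 0.0695 with an estimated correlation). Within that list the endoplasmic reticulum proteins CRELD2 and MANF changed by 1.58 ± 0.09 and 0.84 ± 0.05 at the transcript level. XAF1 and CRELD2 share reads with other genes.

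Replication genes were below control in 24 of 46 cases and above it in 3, with a median of -0.22 (camera adjusted p = 0.000159, and 0.125 with an estimated correlation). The sliding clamp gene PCNA changed by -0.64 ± 0.05 (SE), with shared reads. Of 42 mitosis genes, 16 rose and 4 fell (camera adjusted p = 0.182), while with the library of disagreeing labels counted as KD_Rescued the median was -0.25 and the list was called as lower (camera adjusted p = 0.00831), and without shEV replicate 3 it was called as higher (camera adjusted p = 0.0497). Ribosomal protein genes were lower in 30 of 52 cases and higher in 0, with a median of -0.22 (adjusted p = 0.401 with an estimated correlation). Immediate early genes were lower in 9 of 19 cases and higher in 1 (adjusted p = 0.110 with an estimated correlation), with FOS at -5.62 ± 0.25 and DUSP1 at -2.41 ± 0.08. Plasma cell identity genes fell in 19 of 33 cases and rose in 10 (adjusted p = 0.110 with an estimated correlation). MYC targets fell in 14 of 40 cases and rose in 3, glycolysis and hypoxia genes fell in 11 of 28 and rose in 4, and oxidative phosphorylation genes fell in 14 of 41 and rose in 4, with adjusted p = 0.401, 0.401 and 0.402 with an estimated correlation. The preset-correlation call of the MYC targets was lost without shEV replicate 2 (camera adjusted p = 0.0549), and that of the glycolysis list without PHF19_KD replicate 2 or KD_Rescued replicate 2 (camera adjusted p = 0.0557 and 0.0657). A filter at 5 CPM ended all 3 calls (camera adjusted p = 0.0797 for the MYC targets, 0.0578 for glycolysis and 0.0797 for oxidative phosphorylation). The calls of the replication and immediate early lists were lost when the library with disagreeing labels was counted as PHF19_KD (camera adjusted p = 0.250 and 0.0687), at medians of -0.26 and -0.17, and those of the unfolded protein response and ribosomal protein lists when it was counted as KD_Rescued (camera adjusted p = 0.213 and 0.682), at medians of 0.12 and -0.0182. Counting it as KD_Rescued also ended the immediate early and glycolysis calls (camera adjusted p = 0.138 and 0.134). Among the genes, PCNA lost its call when that library was counted as PHF19_KD, at a log2 fold change of -0.69, and MANF, DUSP1, DOCK1, STX16-NPEPL1 and ATP5A1P2 when it was counted as KD_Rescued. Adjusted over the list alone, the counts of the lists named for this comparison were the same except for 13 rises in the MHC class II list, 26 falls in the replication list and 10 falls in the immediate early list.

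The largest single rises over shEV were those of COL6A3 (6.97 ± 0.63, log2 and SE), ADAMTS2 (5.37 ± 0.27), UBD (3.66 ± 0.73), MAMDC4 (from 1.65 ± 0.210 to 13.3 ± 0.327 CPM, SD) and RHPN1 (2.83 ± 0.10). RP11-514P8.8, STX16-NPEPL1, HLA-DQA2, MST1L and LINC00893 also met the rule and share reads, as do the counts of MAMDC4, and the call of RP11-514P8.8 was lost without shEV replicate 1, shEV replicate 2, KD_Rescued replicate 1 or KD_Rescued replicate 2 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0512, 0.0538, 0.0506 and 0.0877) and with limma-voom (Benjamini-Hochberg adjusted p = 0.138). The largest falls after FOS were those of SLC17A9 (-4.50 ± 0.29), FES (-3.99 ± 0.37), DOCK1 (-3.83 ± 0.43), SECTM1 (-3.37 ± 0.13), the RNA-editing enzyme gene ADARB1 (-3.05 ± 0.12) and AHNAK, which went from 200 ± 10.3 CPM in shEV (SD, n = 3) to 25.8 ± 0.0559 CPM in KD_Rescued (SD, n = 2). SNURF and ATP5A1P2 met the rule and share reads.

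In all, 6599 genes differed between KD_Rescued and shEV, 3436 higher and 3163 lower (edgeR quasi-likelihood, Benjamini-Hochberg), and 1216 of them by at least 2-fold, 906 up and 310 down. The majority direction depended on the processing, with 3006 higher and 3866 lower under RLE scaling, 2231 and 3049 with DESeq2, and 3277 and 4112 without a filter. Of the 6599, 3823 (57.9%) had been called in the same direction in the knockdown, 1357 (20.6%) in the opposite direction, and 1419 (21.5%) had not been called there. The independent expectation for calls in the same direction was 2282, and both comparisons contain the shEV libraries. With these parted in the same manner, from 2108 to 4020 genes were called in the same direction, against an independent expectation of 1185 to 2456. The total was 4253 without KD_Rescued replicate 1 and 4048 without KD_Rescued replicate 2, and 4047 or 2464 with the library of disagreeing labels counted as PHF19_KD or KD_Rescued. Mitochondrially encoded genes took 5.08% ± 0.132 of the counts in KD_Rescued (SD, n = 2), and lane and rescue cannot be told apart in this comparison.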

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

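The tests in this part were chosen after the data were seen. In the library with disagreeing labels, which entered no comparison, 1 gene was at least 4-fold above every other library at 1 CPM or more, and 5 genes were at least 4-fold below every other library. The gene above was AOC1, which encodes an amine oxidase and was singled out after its values were seen, at 5.62 CPM against at most 0.837 CPM elsewhere. Only the 16600 tested genes, filtered on the other 8 libraries, were searched. Genes near silent in those libraries were left out beforehand, so the count of genes above cannot show how many are particular to this library.

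The same library lay between the groups on the first principal component (19.6, against at least 58.4 in PHF19_KD and at most -34.1 in the other groups) and on the knockdown side of shEV for 93.2% of the 4383 genes changed at least 2-fold by the knockdown, but it also stood apart, at -35.2 on the third component (5.82% of the variance) against -1.56 to 7.44 for all other libraries, with MX1 at 73.6 CPM above every other library. Of 12586 genes, 508 were at least 2-fold away from the PHF19_KD mean, against at most 46 for a PHF19_KD library, and 1203 from the KD_Rescued mean, against 28. The spread within groups may be technical, so these values leave membership of either group open. The library name begins with MMCL and a number, as do the PHF19_KD names with another number, while the KD_Rescued names do not. It also gives the lane of all libraries but the KD_Rescued ones, so the name goes with the title. A first test of whether the library was a mixture of RNA from the other groups excluded nothing, since 13 genes lay at least 2-fold outside the range of the other 8 libraries, against up to 12 for those libraries. The genes counted were chosen by their levels in those 8 libraries. Genes expressed in the disputed library alone were thus left out, and its count is not strictly comparable with theirs. In a second test, the MYC targets needed a PHF19_KD share of at least 84.2% (lower quartile). The cell cycle genes allowed at most 77.1% (upper quartile), in the same order with RLE and upper-quartile scaling. These lists were chosen after the first result and the list medians were seen, and the medians already gave this order. The second test thus cannot decide, and a mixture stays open. A separate knockdown culture with milder depletion, or a rescued one with less PHF19, could give such values and was not tested.

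For the breadth of the knockdown response, the splits of the 6 libraries were too few for a share under 0.05, with 1 of 10, the real one, at 11476 genes, while the others gave 0 calls with edgeR and at most 335 genes at an unadjusted p below 0.05. Those other splits mix shEV and PHF19_KD libraries within each group. The differences between the real groups then enter the spread, so the lack of calls there carries no support. Library depth, lower in PHF19_KD, was not the source, because 10628 genes changed after thinning to equal depth. For a common source with the mitochondrial share, the cell cycle genes were assumed to fall in proportion to the log2 rise in share. That rule would place them at or below -1.25 in KD_Rescued, at a share of 5.08%, yet their lower quartile there was -0.25. In the library with disagreeing labels, at a share of 5.56%, their median log2 ratio to shEV was -1.32. The KD_Rescued values thus argue against this rule for that group only, and a link with the share stays open. A property of a single derived line may contribute and cannot be told apart from the knockdown, since the 3 libraries share a name stem and the only other library with a knockdown title, where the cell cycle genes had a median log2 ratio to shEV of -1.32, has disagreeing labels.

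For the difference between KD_Rescued and shEV, incomplete return cannot be the source of every change, because 20.6% of the changed genes had been called in the opposite direction in the knockdown. Incomplete return for part of them and PHF19 above its control level stay open, since the 57.9% called in the same direction share the shEV libraries and which way excess PHF19 moves genes was not tested. The covariance of both comparisons with shEV exceeded the simulated mean by 0.26 and lay above every simulated value, but their correlation, 0.34, lay below every simulated value (lowest 0.37). The simulated groups held no effects, so their correlation came from shared noise alone. Effects particular to a comparison would lower it, so the lower observed correlation decides nothing. With the shEV libraries parted so that none was in both comparisons, the correlation was from 0.23 to 0.27, which leaves out noise of single libraries but not what the shEV libraries have in common. Sequencing lane cannot be told apart from rescue, because no group was run in both lanes. It may contribute to any of the 6599 calls, among them the 1419 genes not called between PHF19_KD and shEV.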

How the results depend on the processing

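Thinning to equal depth, removing mitochondrially encoded genes and parting shared libraries were chosen after seeing the data. Across all alternatives but the 2-fold minimum, the genes changed between PHF19_KD and shEV numbered from 8960 to 12201, within 1.5 times the 11476. A 2-fold minimum, which by construction can only remove calls, left 4383 (2712 up, 1671 down), 3849 between KD_Rescued and PHF19_KD (1747 up, 2102 down), 1216 between KD_Rescued and shEV (906 up, 310 down), and 2796 genes moved back. Counting the library with disagreeing labels as PHF19_KD gave 4047 genes between KD_Rescued and shEV (1862 up) and a PHF19 log2 fold change of 0.86 that was no longer called. Counting it as KD_Rescued gave 6207 genes between KD_Rescued and PHF19_KD (3338 up, 2869 down), 2464 between KD_Rescued and shEV (1262 up, 1202 down), 5400 moved back and a PHF19 change of 0.49, no longer called. DESeq2 called 2231 genes higher and 3049 lower in KD_Rescued than in shEV, at a median log2 fold change of -0.0317 over all genes. With only the scaling changed to RLE, edgeR also called more genes lower (3866) than higher (3006), at a median of -0.0312. A change of scaling was thus enough for the lower majority. The cause of the smaller number of calls with DESeq2 was not tested. Of the list tests, 39 passed with camera, 10 with an estimated correlation and 78 with fry, which does not compare a list with other genes.

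Leaving out 1 library at a time gave 4048 to 7539 genes between KD_Rescued and shEV, with 2168 to 3714 higher and 1880 to 3825 lower. The total was 4253 without KD_Rescued replicate 1, 4048 without KD_Rescued replicate 2 and 7539 without shEV replicate 3. Without a KD_Rescued library, the lone remaining one is assumed to vary like the other groups. Replicate numbers did not pair the samples, with residual correlations from -0.01 to 0.03 for the same number, and a replicate block gave 11537, 10341 and 6387 changed genes. Among single genes and lists called in the main fit or the alternative, the sign changed only with the disputed library. Counted as KD_Rescued, it put the mitosis list at -0.25 against shEV, now called as lower, B2M at 0.14, POLE at -0.0407, NOP2 at -0.0304 and HIST1H2AC at 0.0362. Counted as PHF19_KD, it put FN1 at 0.0402 against shEV. None of these 5 genes was called there, so their calls were lost and not turned. The cause was not tested. Of the other values of named genes under alternatives, 174 lost the call and 6789 neither lost nor gained one. The latter include genes called in neither fit, whose direction was not checked. The pseudocount alternative was not run, since the file holds counts. At the depth of these libraries, the simulation recovered 34% of the genes with the smallest simulated change and 88% of 2-fold changes. Few genes were changed in it, so these shares do not carry over to the data.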

Other observations

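The gene groups and tests in this part were chosen after the data were seen, except the lists fixed beforehand. All 13 mitochondrially encoded mRNAs rose in PHF19_KD, with a median log2 fold change of 1.48, and all 13 stayed above shEV in KD_Rescued, with a median of 0.75. The mitochondrial ribosomal RNA MT-RNR2 went from 2024 ± 164 CPM in shEV to 12038 ± 473 CPM in PHF19_KD (SD, n = 3 each) and stood at 4248 ± 148 CPM in KD_Rescued (SD, n = 2), with shared reads, while the nuclear-encoded oxidative phosphorylation genes had a median of -0.46 in the knockdown. Immunoglobulin genes took 2.74% ± 0.168 of the counts in shEV, 1.44% ± 0.0389 in PHF19_KD (SD, n = 3 each) and 2.04% ± 0.0856 in KD_Rescued (SD, n = 2), with shared reads in this family.

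At equal depth, 21871 ± 152 genes had a count in shEV, 23421 ± 69.9 in PHF19_KD (SD, n = 3 each) and 22536 ± 86.3 in KD_Rescued (SD, n = 2). With all libraries of a group below 0.2 CPM and all of the other at 1 CPM or more, 53 genes were on and 23 off in PHF19_KD, so that 69.7% were on. The larger number of detected genes already favours the first set, so this is no separate test. Of the 53, 23 were below 0.2 CPM in both KD_Rescued libraries, and 13 of the 23 were back at 1 CPM or more. None of either set was in the developmental Polycomb target list (0 and 0 genes). Only 37 of the 16600 tested genes were in that list, so sets this small would hold few or none by size alone. The B-lineage receptor genes FCRL1 and FCRL2 were among those on, at 3.52 and 2.96 CPM in PHF19_KD, as were PIGR at 4.95 CPM and APOE at 1.63 CPM, each named after its values were seen.

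In the library with disagreeing labels the gene groups moved by unequal amounts relative to shEV. The median log2 ratios were 0.82 for interferon-stimulated genes and -0.75 for MYC targets, against 0.81 and -0.78 in PHF19_KD and 0.21 and -0.0754 in KD_Rescued on the same scale. Cell cycle lists stood at -1.44 for replication and -1.11 for mitosis, against -3.02 and -2.75 in PHF19_KD and -0.21 and 0.06 in KD_Rescued. Immediate early genes stood at -0.13, against 0.67 in PHF19_KD and -0.12 in KD_Rescued. The MAF list stood at 0.38, against 0.01 and -0.02, and the fibroblast markers at 0.42, against -0.19 and -0.29, outside both groups.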
